A study of Mus musculus with 5 samples.

How the data were processed

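The values were deposited as tables of normalized UMIs (unique molecular identifiers, one per captured transcript) with 36529 gene rows, 1 table for each islet library and 1 for the 3 tumor libraries. Per the file headers the authors divided each cell's UMIs by the cell's total and multiplied by a constant, so the unit is a signal and not a count; the cell totals in the headers are counts. The constant was 9936 in both islet tables and 12219 in the tumor table. The islet headers name the total of all UMIs and the tumor header that of exonic UMIs. The submitters' processing notes name CASAVA 1.8, bcl2fastq 2.17 and GSNAP 2013-10-10 and the genome build GRCm38; the role of each tool is not given in the sources used here.

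Whole UMIs were recovered by multiplying back, and 100.0% of the values came out whole within 0.01. The recovered sum of a cell was 1.0141, 1.0196 and 1.0275 times the authors' total (medians for the heterozygous, homozygous and tumor cells). Levels and ratios of islet cells are UMIs per 1000000 recovered UMIs (CPM). For the tested comparisons each cell's recovered UMIs were scaled to CPM by the authors' total of that cell. The design had foreseen counts and edgeR; since the unit differed, limma became the main test and edgeR and DESeq2 on recovered UMIs became alternatives. The count test (edgeR with TMM) called 26 genes higher and 9 lower in tumors, and 51 higher and 31 lower in Slc38a5-positive cells. Of the gene rows, 31049 (85.0%) matched the annotation by Entrez identifier, and positions are those of GRCm38.

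Cells needed 1000 UMIs, 500 genes and at most 20% mitochondrial UMIs, and no deposited cell failed. Scrublet (expected rate 0.06) called 8, 1, 17, 9 and 15 doublets in the heterozygous, homozygous and tumor A, B and C libraries, and these were removed, which left 1326, 2843, 496, 846 and 1084 cells. Total UMIs were 22174810, 34101553, 10508498, 22893238 and 22161240. Alpha-like cells were the cells the authors typed as alpha in islets and all kept tumor cells. As a check, UMIs of all 8 alpha cell markers were found in each main alpha or tumor cluster, and cluster 2 of tumor library C was the 1 cluster with none among its top 10 genes. A marker counted as found with any UMI summed over the cluster, which background can give, so that part of the check cannot show the cell type.

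For the tested comparisons, the mean CPM over cells was taken per library, log2-transformed with a pseudocount of 1 CPM, and fitted with limma 3.58.1 (trended prior variance) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. Fold changes on this scale understate the change of genes near 1 CPM. Genes needed 5 CPM in 2 libraries. The positive and negative cells were compared within libraries, without Slc38a5 itself, with library as a block and 20 cells or more per class. P-values rest on spread between libraries and not between cells, but limma draws the variance of each gene in part from all genes. With few libraries this shared part weighs heavily, most of all in the positive against negative fit. A small p-value there does not show that the libraries gave like changes. The tumor libraries came from 3 animals, and each islet genotype had 1 library, so the islet arm of the tumor comparison mixes genotypes. For the islet genotypes only ratios with exact intervals (95%) were computed, with no test. A count of 0 was given the limit of 3 counts.

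Fixed gene lists (13, from amino acid transporters to mitochondrially encoded genes) and 18 lists of cell type markers were used, of whose symbols 5 were missing. The lists were tested with camera (preset correlation 0.01, then estimated). For the islet ratios a list's median was ranked among 10000 random lists matched on expression. Cycling cells had UMIs of 2 or more of 11 cycle genes after thinning to 5000 UMIs. Named genes were the 12 each way with the largest change among those past the threshold and changed alike in every library, with 50 CPM or more in 1 arm and no predicted symbol, up to 4 past the threshold per list, and Gcgr, Gcg and Slc38a5. For islet ratios they were those with 50 CPM or more in 1 genotype and an interval bound beyond 1.5-fold, ranked by that bound. Gene lists, comparisons, thresholds and the rule for named genes were set before the data were examined.

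A self-test on simulated libraries recovered 43.3%, 98.5% and 100% of genes changed by log2 1, 2 and 4 in the tumor design (dispersion 0.05, 17 false among 178 calls) and 64.6%, 97% and 100% in the positive against negative design (dispersion 0.01, 10 false among 182). At a dispersion of 0.2 the tumor design recovered 1.5%, 37.5% and 100%, and at 0.05 the positive against negative design recovered 9.4%, 89.4% and 100%. The ratio rule recovered 92.5%, 100% and 100% with 0 false calls. Its simulation drew Poisson counts, with the same rate in both libraries for unchanged genes and no variation between animals or in handling. The 0 false calls thus cover counting error only. Alternatives were edgeR 4.0.16, DESeq2 1.42.0, TMM scaling, totals without 8 hormone transcripts, no low filter, a pseudocount of 10, 2000 or more UMIs per cell, doublets kept, deposited values as they are and leaving out each library. Clustering was not repeated, since the authors' types were used. Genes that share sequence with a copy or pseudogene, and pairs that overlap on opposite strands, cannot be separated in these tables. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 and matplotlib 3.10.9.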

Results

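Single-cell RNA-seq libraries were made from the islets of a mouse heterozygous for a knockout of the glucagon receptor gene Gcgr (1 library), from the islets of a homozygous knockout (1 library) and from pancreatic tumors of Gcgr knockout mice (3 libraries from 3 animals, called tumor libraries A, B and C here). The title of the series asks which alpha cells, the glucagon-producing cells of the islet, give rise to the tumors when the receptor is lost, and how amino acids take part. The heterozygous islet library held 22174810 UMIs in 1334 cells, with a median of 15017 per kept cell. In the homozygous islet library 34101553 UMIs fell on 2844 cells, with a median of 10961. Tumor library A held 10508498 UMIs in 513 cells (median 19867.5), tumor library B 22893238 in 855 cells (median 26091.5) and tumor library C 22161240 in 1099 cells (median 19378.5). After doublets were removed, 1326, 2843, 496, 846 and 1084 cells stayed, in that order of libraries. Levels are UMIs of a gene per 1000000 UMIs of the named cells (CPM); in the tested comparisons they are means over cells of CPM by the authors' cell totals. With 1 library per islet genotype the exact Poisson intervals (95%) of levels and the exact binomial (Clopper-Pearson) intervals of shares cover counting error only.

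Gcgr, the receptor targeted by the knockout (chromosome 11, 120529185 to 120538989 in GRCm38), was detected with 137 UMIs in the heterozygous islet library, or 6.21 CPM (5.22 to 7.35). No Gcgr UMI was found among 34091060 in the homozygous islet library, which allows up to 0.088 CPM. In tumor library A no UMI of Gcgr was found either, which allows up to 0.297 CPM, while tumor library B held 1 UMI (0.0443 CPM, 0.00112 to 0.247) and tumor library C held 3 (0.138 CPM, 0.0284 to 0.403). Within the heterozygous library Gcgr stood at 7.18 CPM in beta cells (5.97 to 8.56) and at 2.49 in alpha cells (1.07 to 4.90), against 2.34 in endothelial cells (0.284 to 8.46; 2 UMIs). Gcg, which encodes proglucagon, took 339500 CPM of the UMIs of heterozygous alpha cells and 326400 of those of homozygous alpha cells. The cells of tumor libraries A, B and C gave Gcg at 364400, 284200 and 312500 CPM.

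The first comparison asks how the cell types of the islet differed between the genotypes. By the authors' annotation, alpha cells made up 23.1% (20.8 to 25.4) of the heterozygous library and 53.6% (51.8 to 55.5) of the homozygous one. Insulin-producing beta cells were 51.7% (49.0 to 54.5) of heterozygous and 16.2% (14.9 to 17.6) of homozygous cells. The somatostatin-producing delta cells went from 4.68% (3.60 to 5.95) to 11.7% (10.5 to 12.9). Pancreatic polypeptide (PP) cells were 0 of 1326 heterozygous cells, which allows up to 0.226%, and 5.31% (4.52 to 6.20) of homozygous cells. The 0 rests on the authors' typing, since 2 heterozygous cells typed as alpha (cluster 1.7) held the PP hormone transcript Ppy at 421900 CPM and Gcg at 6731. In the homozygous library 15 cells typed as alpha (cluster 2.6) held Ppy at 361300 CPM and Gcg at 107000. Endothelial cells were 14.7% (12.8 to 16.7) against 7.53% (6.58 to 8.56), and stellate cells 2.49% against 2.60%. Macrophages were 3.32% of heterozygous cells and 0 of 2843 homozygous cells, which allows up to 0.106%. In the homozygous library, a type the authors left unnamed (3.03% of cells) held C1qa, C1qb and C1qc, which encode the complement component made by macrophages, at 7708, 9181 and 5898 CPM, against 7398, 8497 and 5483 in the heterozygous macrophages. The macrophage genes Cd74 and Lyz2 stood at 27400 and 4018 CPM in it, against 87810 and 2098 in the heterozygous macrophages. Among endocrine cells alone, alpha cells were 29.0% (26.3 to 31.9) in the heterozygous and 61.8% (59.8 to 63.7) in the homozygous library. The genotype difference rests on 1 library each and has no replicate check.

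**Figure D1:**
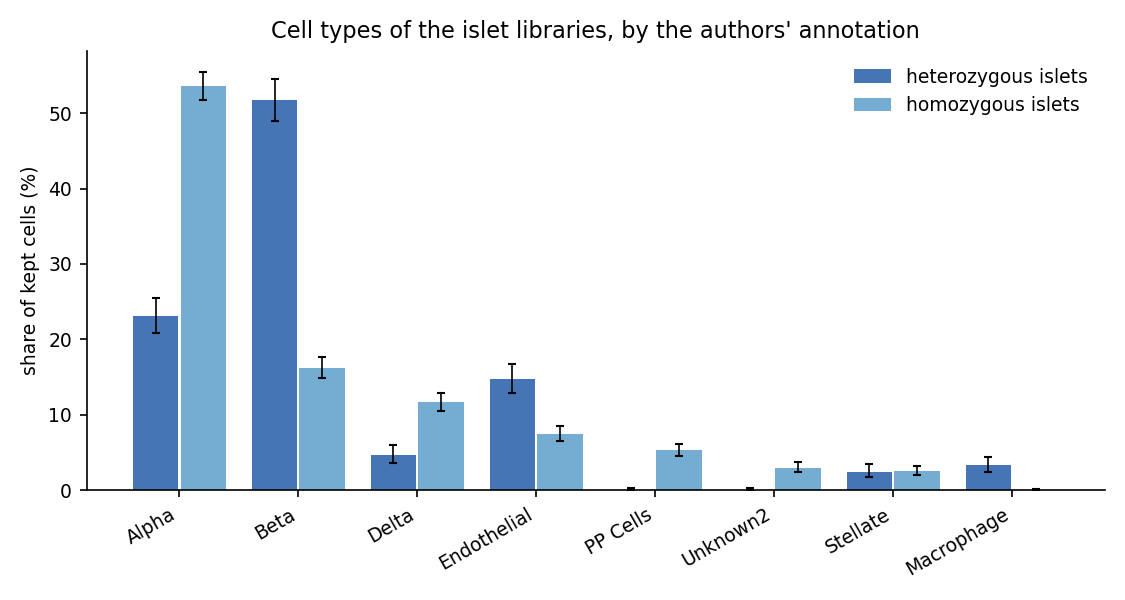
Share of kept cells (%, bars) by cell type of the authors' annotation in the heterozygous and homozygous islet libraries, with exact binomial 95% intervals as error bars. Alpha cells stand at 23.1% and 53.6%, beta cells at 51.7% and 16.2%.

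Alpha cells of homozygous islets were then set against those of heterozygous islets. Nearly all heterozygous alpha cells lay in the authors' cluster 1.2 (304 cells), while homozygous alpha cells lay in cluster 2.1 (947 cells), cluster 2.2 (563 cells) and cluster 2.6 (15 cells). The median gene with 50 CPM or more stood at 0.857 times its heterozygous level (log2 ratio -0.22, over 1952 genes), and at a log2 ratio of 0.03 when 8 hormone transcripts were left out of the totals. Slc38a5, a transporter of glutamine and other neutral amino acids (chromosome X, 8271381 to 8280179), stood at 96.7 CPM (86.3 to 108.1) in heterozygous and 766 CPM (755 to 778) in homozygous alpha cells, a ratio of 7.92 (7.08 to 8.89). Cluster 2.1 carried most of it, with 1087 CPM against 195 in cluster 2.2. In endothelial cells, which should lack it, Slc38a5 stood at 1.17 CPM in the heterozygous and 28.3 in the homozygous library. The secretin gene Sct had a ratio of 32.6 (13.9 to 100.6), Vgf, the precursor of neuroendocrine peptides, one of 9.86 (7.27 to 13.7), and Spp1, which encodes osteopontin, one of 13.2 (11.3 to 15.5). Eef1a2, a translation elongation factor of neurons, muscle and endocrine cells, had a ratio of 25.4 (18.8 to 35.1). The remaining genes at that end were Ttyh1 (21.7), the imprinted gene Mest (19.7), Basp1 (9.15), Dapl1 (8.49), the apolipoprotein gene Apoa2 (6.93) and the protease inhibitor gene Serpine2 (6.54). In cluster 2.1 alone Sct stood at 71.8 CPM, Ttyh1 at 77.6, Mest at 80.4 and Dapl1 at 1738, against 13.0, 12.0, 10.5 and 377 in cluster 2.2. Vgf, Eef1a2, Apoa2 and Serpine2 were also higher in cluster 2.1, while Basp1 (179.3 and 180.0 CPM) and Spp1 (662.9 and 619.4) hardly differed. The acinar gene Ctrb1 had the largest ratio, but its level of 71.4 CPM in homozygous alpha cells lay below the 244 of endothelial cells of that library.

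At the low end stood immediate early genes, which are switched on within minutes of a stimulus or of tissue handling. Fos stood at 1413 CPM in heterozygous and 145 in homozygous alpha cells, a ratio of 0.103 (0.0984 to 0.108). Ratios of the others were 0.0460 for Atf3, 0.0716 for Egr1, 0.0753 for Ier2, 0.0881 for Junb, 0.0895 for Dusp1 and 0.103 for Fosb. In endothelial cells of the same libraries Fos stood at 1394 and 1353 CPM and Junb at 1797 and 1576. Other genes at this end were the atypical kinase Mapk15 (0.0476), the potassium channel subunit Dpp10 (0.0572), the endothelin Edn3 (0.0764), the metallothionein Mt2 (0.0933) and the arginase Arg1 (0.101).

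By fixed list, the 16 stress and immediate early genes had a median log2 ratio of -2.60 relative to all genes, below all 10000 random lists matched on expression (percentile 0.00). The amino acid transporter list had a relative median of -0.80 (percentile 0.01), so Slc38a5 stood apart from it: Slc7a8 had a ratio of 0.223, Slc7a2, which carries arginine and other cationic amino acids, 0.244, and Slc38a2 0.259. The islet transcription factors had a relative median of -0.67 (percentile 0.00), with ratios of 0.406 for Meis2, 0.449 for Neurod1 and 0.475 for Foxa2. Genes of hormone processing and secretion had a relative median of -0.35 (percentile 0.25). Among them Pcsk2, the convertase that makes glucagon, stood at 0.446, Pcsk1n, which encodes an inhibitor of a related convertase, at 0.335 and G6pc2 at 0.269, against the high ratio of Vgf. In endothelial cells G6pc2 also fell, from 39.8 to 12.4 CPM, against 67.2 and 18.05 in alpha cells, so background may account for part of its ratio. Pcsk1n and Pcsk2 changed less there (340.7 to 264.9 and 105.4 to 95.4 CPM). The ribosomal protein genes had a relative median of -0.25 (percentile 0.00), with Rps16 at 0.461, Rps12 at 0.483, Rps24 at 0.519 and Rpl9 at 0.516. These genes were lower in homozygous endothelial cells too. There Rps16 went from 236.5 to 107.7 CPM, Rps12 from 144.0 to 114.8, Rps24 from 686.1 to 429.2 and Rpl9 from 227.1 to 153.7. Unfolded protein response genes had a relative median of 0.39 (percentile 99.4), with Pdia6, a folding enzyme of the endoplasmic reticulum, at 1.68. For peptide hormones the relative median was 0.56 (percentile 98.0). Ppy and Pyy, which encode the peptides of PP cells and of the gut, stood at 4.79 and 4.28 times, with 10590 and 5506 CPM in endothelial cells of the homozygous library against 76620 and 83480 in alpha cells. These levels are pooled over cells; the median alpha cell held Ppy at 1884 CPM in the heterozygous and 27460 in the homozygous library, and Pyy at 9553 and 66370. Ins1 and Ins2 had ratios of 0.188 and 0.173, and their alpha cell levels followed the endothelial background, with Ins2 at 38150 in heterozygous alpha and 33440 in heterozygous endothelial cells, and at 6605 and 5239 in the homozygous library. The remaining lists lay between the 19.99 and 92.5 percentiles: ATF4 targets -0.19 (44.1), cell cycle -0.12 (51.6), neuroendocrine tumor suppressors -0.27 (29.0), antigen presentation 0.13 (92.5), hypoxia -0.35 (19.99) and mitochondrially encoded genes 0.10 (52.9). Before the shift of all genes was taken off, antigen presentation and mitochondrially encoded genes had medians below 0 (-0.09 and -0.13). Single members of these lists that met the size rule were Atf4 (0.325), the cyclin gene Ccnd2 (1.84), the cell cycle inhibitor gene Cdkn1a (2.47), Cd74 (0.352), Ndrg1 (0.215) and ND2 (0.514). In endothelial cells ND2 fell by a like ratio (128.8 to 68.9 CPM), Atf4 fell less (266.9 to 199.6) and Cd74 hardly (76.1 to 74.2). Ndrg1 rose there (190.8 to 296.7), as did Cdkn1a (357.1 to 499.9), and Ccnd2 hardly changed (498.8 to 510.5).

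The share of alpha-like cells with a Slc38a5 UMI was compared after each cell was thinned to 5000 UMIs. It was 22.8% (17.8 to 28.4; 59 of 259 cells) in heterozygous and 69.8% (67.3 to 72.2; 996 of 1427) in homozygous islets. Tumor libraries A, B and C had 89.2% (86.0 to 91.8), 97.0% (95.7 to 98.1) and 96.4% (95.2 to 97.5), a mean of 94.2% ± 4.38 (SD, n = 3). Beta cells of the same islets, taken as background, had 0.882% (0.325 to 1.91) and 14.2% (11.0 to 17.8). Median depths before thinning were 10002.5 UMIs for heterozygous alpha and 26444 for beta cells, and 14086 and 10854 in the homozygous library. Without thinning the alpha-like shares were 40.9%, 82.8%, 97.2%, 99.8% and 99.5%. The beta cell shares were then 4.956% in heterozygous and 37.96% in homozygous islets. Thinning left out 47, 98, 16, 4 and 16 alpha-like cells. Cells with UMIs of 2 or more of 11 cycle genes, such as the proliferation marker Mki67 and the mitotic kinase Cdk1, were 0.772% (0.0937 to 2.76; 2 cells) of heterozygous and 0.491% (0.197 to 1.01; 7 cells) of homozygous alpha cells. In the tumors they were 6.46% (4.43 to 9.04), 5.23% (3.82 to 6.95) and 6.84% (5.40 to 8.52), a mean of 6.17% ± 0.842 (SD, n = 3). The tumor shares lay above both islet shares by more than their intervals, with no test between single islet libraries, and unthinned they were 11.5%, 10.1% and 14.0% against 0.654% and 0.787%. With 3 or more cycle genes the interval of tumor library B (2.61 to 5.32) overlapped that of heterozygous alpha cells (0.0937 to 2.76). The intervals of tumor libraries A and C did not.

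**Figure D2:**
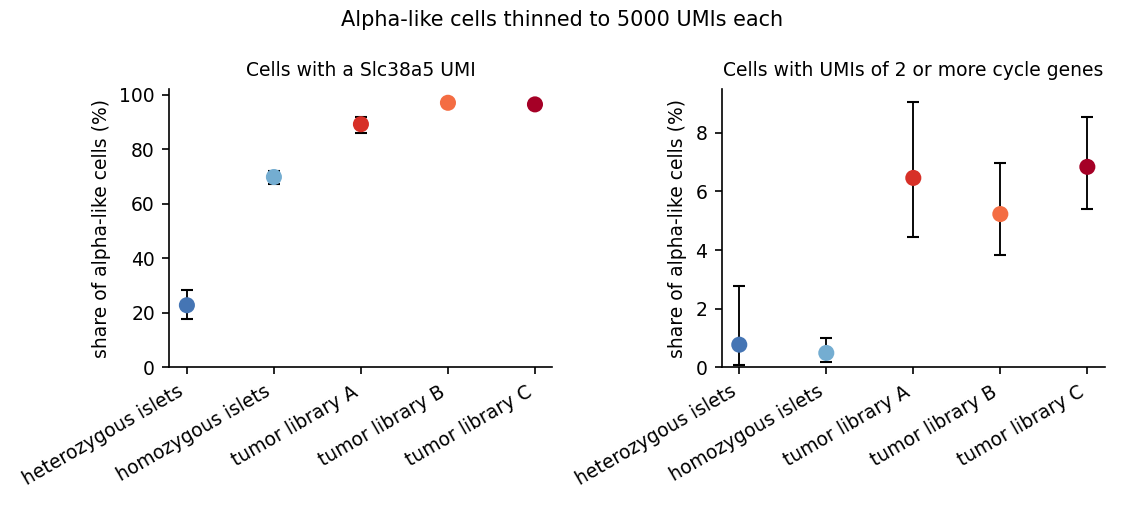
Share of alpha-like cells (%) with a Slc38a5 UMI (left) and with UMIs of 2 or more cycle genes (right) in each library after thinning to 5000 UMIs per cell; points are libraries and error bars exact binomial 95% intervals. The cycle gene share lies at 0.772% and 0.491% in the islets and between 5.23% and 6.84% in the tumors.

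The tumor comparison asks what set tumor cells apart from alpha cells of the islets (3 tumor libraries, all kept cells, against the alpha cells of both islet libraries). Of 10234 genes tested with limma, 213 were higher and 14 lower in tumors. The median gene was higher by 0.25 (log2), so the log2 changes below are relative to that median. All named genes that passed differed in the same direction in every tumor library from both islet libraries. Among genes of transcription factors, Fosl2 rose by 4.11 ± 0.35 (SE, adjusted p = 0.00502), Fosb by 3.62 ± 0.72 (adjusted p = 0.0390), Nr4a1 by 2.87, Srf by 2.49 and Irf1 by 2.42. Fosl2 went from 1.38 and 3.86 CPM in the islets to 71.1, 54.1 and 83.1 in the tumors. Nfkbia, which encodes an inhibitor of NF-kappaB, rose by 3.00 ± 0.45 (adjusted p = 0.0247). Further genes that rose were the RNA sensor Ifih1 (2.30), the kinase subunit Prkab2 (2.31), Tppp3 (2.37), C2cd4b (2.29) and the small mitochondrial ribosomal RNA Rnr1 (2.89). Among the genes that fell were Ppy (-5.99 ± 0.92), the heat shock gene Hspa1a (-4.89 ± 0.85), the tight junction gene Cldn7 (-3.13), Rgs2 (-2.23), the pseudogene Pisd-ps3 (-2.23), Gstt1 (-1.94), the vesicle gene Rab3a (-1.68) and Wnt4 (-1.58). The change of Ppy rests on means over cells. The median cell held Ppy at 1884 and 27460 CPM in heterozygous and homozygous alpha cells, and at 472.0, 80.9 and 124.2 in tumor libraries A, B and C. Endothelial cells of the islet libraries held 631.1 and 10590 CPM, so background may account for part of its islet level. After trimmed mean of M values (TMM) scaling, Fosl2, Nfkbia, Rnr1, Nr4a1, Srf, Prkab2, Rgs2, Pisd-ps3 and Rab3a kept an adjusted p under 0.05. The other genes named so far missed it, from 0.0505 for Gstt1 to 0.106 for C2cd4b, with 0.0796 for Fosb, 0.0938 for Irf1, 0.0680 for Ppy, Hspa1a and Tppp3, 0.0668 for Cldn7, 0.0647 for Ifih1 and 0.0615 for Wnt4. Gcg did not pass (-0.26 ± 0.81, adjusted p = 0.992). Slc38a5 had a change of 2.32 ± 0.78 and missed the threshold (adjusted p = 0.123), with 84.0 and 741 CPM in the islets against 1097, 1813 and 1644 in the tumors. Gcgr was too low to be tested.

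**Figure D3:**
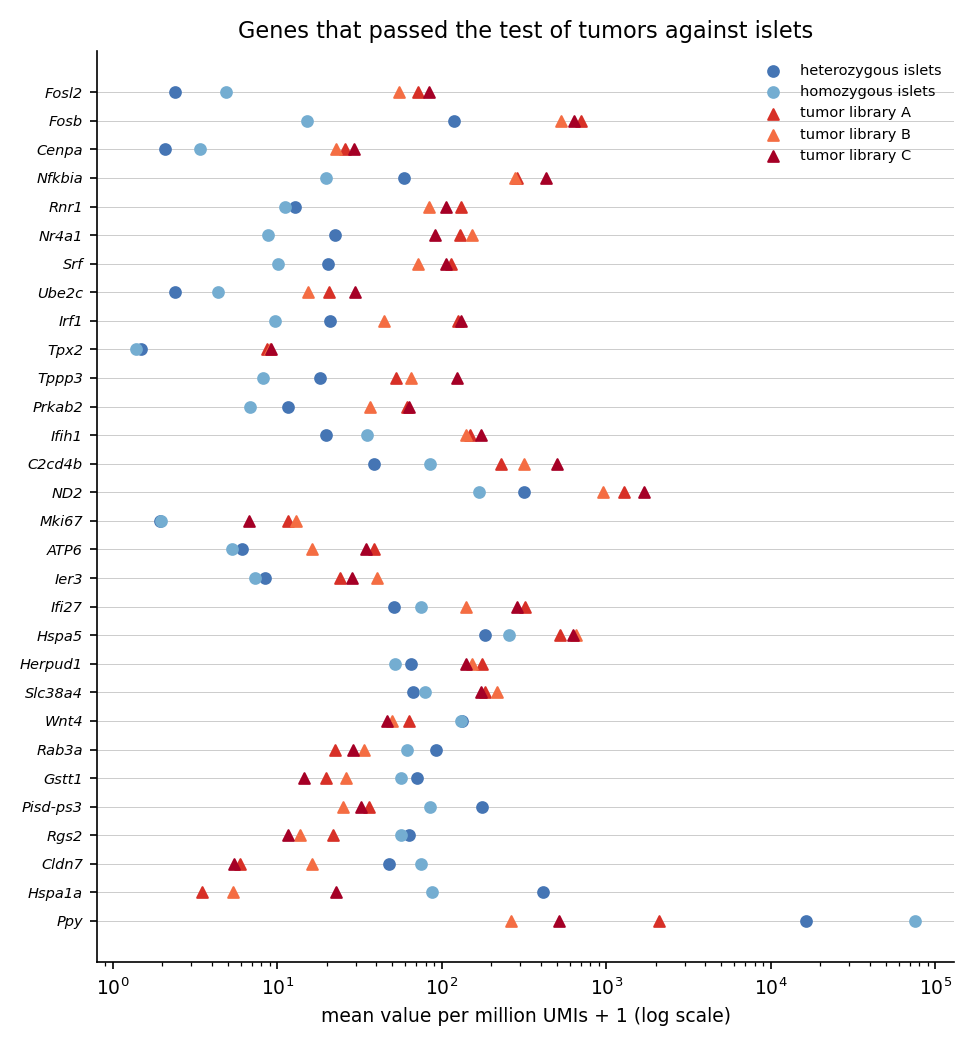
Mean CPM plus 1 (log axis) of genes that passed the test and are named in the text, with 1 point per library (circles islets, triangles tumors). Fosl2 stands at 54.1 CPM or above in all 3 tumors and at 3.86 or below in both islets.

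Of 20 tested cell cycle genes 8 rose (16 adjusted over the list alone) and none fell, with a relative median of 1.77 (camera adjusted p = 2.91e-08, and adjusted p = 0.343 with an estimated correlation). They included the centromere gene Cenpa (3.03), the mitotic genes Ube2c (2.46) and Tpx2 (2.40), and Mki67 (2.12), all from islet levels of 3.37 CPM or lower. Of 16 unfolded protein response genes 2 rose (6 adjusted over the list alone), Hspa5, the main chaperone of the endoplasmic reticulum, by 1.23, and Herpud1 by 1.17 (camera adjusted p = 0.000435, 0.413 with an estimated correlation). Of 10 mitochondrially encoded genes 2 rose (7 over the list alone), ND2 by 2.22 and ATP6 by 2.06 (camera adjusted p = 0.000238, 0.462 with an estimated correlation). The median share of mitochondrial UMIs per alpha-like cell was 0.586% and 0.583% in the islets and 1.25%, 1.18% and 2.00% in the tumors. Of 13 amino acid transporters 1 rose (4 over the list alone), Slc38a4, by 1.14 (camera adjusted p = 0.0405, 0.384 with an estimated correlation). Of 10 peptide hormones 1 fell (6 over the list alone), Ppy, with a relative median of -4.81 (camera adjusted p = 9.70e-06, 0.343 with an estimated correlation). The tested beta cell markers had a relative median of -6.74, the delta markers one of -3.61 and the 6 tested macrophage markers one of 1.11, with no member called; in islet alpha cells the beta cell transcript Ins2 lay near its level in endothelial cells. Of 20 genes of hormone processing 1 fell, Rab3a (camera adjusted p = 0.0405, 0.413 with an estimated correlation). So none of these 6 list calls held with an estimated correlation. Of the members named for them, Cenpa and Rab3a kept an adjusted p under 0.05 after TMM scaling. The others missed it: Ube2c (0.0668), Tpx2 (0.0613), Mki67 (0.0802), Hspa5 (0.154), Herpud1 (0.0873), ND2 (0.0659), ATP6 (0.0713), Slc38a4 (0.130) and Ppy (0.0680). Of 16 stress and immediate early genes 3 rose (Fosb, Nr4a1 and Ier3) and Hspa1a fell, with 4 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.728); after TMM scaling Ier3 had an adjusted p of 0.0647. Of 18 antigen presentation genes 1 rose, Ifi27 by 1.67 (8 over the list alone, camera adjusted p = 0.0526), with an adjusted p of 0.137 after TMM scaling. No member passed among 15 ATF4 targets (2 higher over the list alone), 17 islet transcription factors, 15 neuroendocrine tumor suppressors, 8 hypoxia genes and 83 ribosomal protein genes. Of these, the medians of ATF4 targets, islet transcription factors, hypoxia genes and ribosomal protein genes changed sign with the scaling (0.28, 0.17, 0.10 and 0.12 as tested, -0.01, -0.12, -0.18 and -0.18 after TMM scaling). Of the marker classes, that of PP cells had a called member, Ppy; 5 of the 18 had no tested member.

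The islet and tumor tables were scaled separately by the authors, so these levels rest on recovered UMIs set on 1 scale by the authors' cell totals (all UMIs in the islet headers, exonic UMIs in the tumor header), and tissue and table are confounded. Of the calls, 93.8% were higher, against 79.6% after TMM scaling (35 higher, 9 lower), 74.3% with edgeR (26 and 9), 58.8% with DESeq2 (453 and 318), 81.5% with hormones left out of the totals (44 and 10) and 81.8% with a marker gate, Gcg among the 5 most abundant transcripts of a cell (463 and 103), and without the heterozygous islet library 13 rose and 0 fell (2186 and 68 at an unadjusted p under 0.05 by limma). The gate took in 703 heterozygous and 2539 homozygous islet cells, more than the 306 and 1525 typed as alpha, so its islet arm held many cells of other types. Without the homozygous islet library 51 rose and 2 fell, without tumor library A 29 and 4, without B 142 and 9, and without C 63 and 23.

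Within islets, alpha cells with a Slc38a5 UMI were set against those without one, to ask what else differs between these classes. The split was not thinned, and by the same rule 4.956% of heterozygous and 37.96% of homozygous beta cells were positive. A single UMI may thus be background, and the positive class may include cells that do not carry the transporter. Split at 2 or more UMIs, with tumor library A included, limma called 0 genes (380 higher and 176 lower at an unadjusted p under 0.05). The classes held 125 and 181 cells in the heterozygous and 1262 and 263 in the homozygous library, and tumors had too few negative cells. The classes differed in cluster, with 93.7% of cluster 2.1 and 65.5% of cluster 2.2 positive in the homozygous library, so in that library the contrast overlaps with cluster 2.1 against cluster 2.2. Of 9775 genes tested with limma and library as a block, 20 were higher and 8 lower in positive cells, and each named gene went the same way in both libraries, though not always by like amounts. Rbp4 hardly changed in heterozygous cells (1031 CPM in positive, 990.3 in negative) but did in homozygous ones (1630 and 727.1). Cryba2 also changed less in heterozygous cells (547.0 and 462.0, against 584.3 and 231.5). Clptm1l changed alike in both (46.24 and 26.3, 57.18 and 30.24), and Eef1a2 changed more in heterozygous cells (19.31 and 9.118, against 379.9 and 286.9). Slc38a5 itself was left out, and the log2 changes are relative to the median of all genes (0.01). Vgf rose by 1.25 ± 0.20 (log2, SE, adjusted p = 7.39e-05), Dapl1 by 1.17 ± 0.15 (adjusted p = 6.07e-07) and Gfra3, a receptor of the GDNF family, by 1.14 ± 0.19. Dapl1 stood at 164.6 CPM in positive and 117.5 in negative heterozygous cells, against 1345 and 360.8 in homozygous cells. Its change thus differed between the libraries by more than its SE shows, since limma drew the variance mostly from all genes. Ids, a lysosomal sulfatase, rose by 0.86, the lens crystallin Cryba2 by 0.77, Apoa2 by 0.80, Clptm1l by 0.83, the calcium pump gene Atp2a3 by 0.71, Eef1a2 by 0.69, Hapln1 by 0.64, Ifi27 by 0.72 and the retinol carrier gene Rbp4 by 0.60. Dapl1, Vgf, Eef1a2 and Apoa2 were also among the genes named for their higher level in homozygous alpha cells. Hspa1a fell by 0.91 ± 0.13 (adjusted p = 8.63e-06), the metallothionein genes Mt2 and Mt1 by 0.69 and 0.57, Egr1 by 0.63 and Fos by 0.60. Gcg had a change of 0.14 ± 0.71 and did not pass (adjusted p = 0.997). Of 16 stress and immediate early genes 3 fell (8 lower and 1 higher adjusted over the list alone, camera adjusted p = 2.29e-11), and of 14 antigen presentation genes 1 rose, the interferon-induced Ifi27 (4 over the list alone, camera adjusted p = 6.93e-07). No single member passed among 9 amino acid transporters (relative median 0.24, camera adjusted p = 0.0369) or 82 ribosomal protein genes (0.04, camera adjusted p = 0.0494), and all 4 list calls ended with an estimated correlation (adjusted p = 0.815). After a thinned split over all 5 libraries the ribosomal protein genes went the other way (lower, camera adjusted p = 0.00267, and adjusted p = 0.721 with an estimated correlation). Antigen presentation genes then missed the threshold (0.0686), and islet transcription factors (0.00537), mitochondrially encoded genes (0.00872), unfolded protein response genes (0.0168) and cell cycle genes (0.0195) were higher, none with an estimated correlation (adjusted p = 0.479 or above). Vgf was the only called member of 20 hormone processing genes (3 higher and 3 lower over the list alone, camera adjusted p = 0.719), and no member of the ATF4, cell cycle, hormone, transcription factor, tumor suppressor, unfolded protein, hypoxia and mitochondrial lists passed (over the list alone 2 transcription factors were higher, and 1 hormone was higher and 1 lower). Among marker classes, Rbp4 stood in the delta list and Apoa2 in the hepatocyte list.

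Positive cells were deeper, with medians of 12446 against 8597 UMIs in the heterozygous and 14895.5 against 10408 in the homozygous library, and the fit has 1 residual degree of freedom, so its spread is mostly that shared by all genes. After a thinned split over all 5 libraries 5 genes were higher and 1 lower (Cryba2, Crip1, Lpl, Peg10 and Fxyd3 higher, Ier2 lower), DESeq2 called 0 (42 higher and 22 lower at an unadjusted p under 0.05) and limma without the library block called 0 (10 and 6), while edgeR called 51 higher and 31 lower.

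Tumor library C held a pair of large clusters in the authors' annotation, cluster 2 (697 cells) and cluster 4 (385 cells), both with Gcg in every cell and UMIs of all 8 alpha cell markers. Detection alone does not set alpha cells apart, since every beta and endothelial cell of the islets also held Gcg UMIs. By level, the 5th percentile of Gcg was 200900 CPM in cluster 2 and 225100 in cluster 4, against 14340 pooled over homozygous endothelial cells. None of the 8 markers was among the 10 genes that set cluster 2 apart from the other islet cell types, against 2 for cluster 4. A set of genes on chromosome 10 stood many times higher in cluster 2 than in cluster 4 or in the other tumors (a comparison chosen after the values were seen, within 1 library and without a test). Of the 20 genes with the highest ratio over the mean of cluster 4 and tumor libraries A and B, 19 lay on chromosome 10, which held 5.72% of the 2203 genes ranked. Mdm2, which encodes the ubiquitin ligase that degrades p53 (chromosome 10, 117688875 to 117710758), stood at 2450 CPM in cluster 2, 168 in cluster 4, 49.5 in tumor library A and 44.9 in tumor library B. Cdk4, the kinase that drives entry into the cell cycle (127063535 to 127067288), stood at 2765, 212, 91.2 and 152. Sf3a2, a splicing factor, stood at 3247, 105, 19.9 and 26.2, and its neighbor Plekhj1 at 6926, 340, 56.3 and 99.9. The surface protein gene Cd24a stood at 3610 against 107 in cluster 4, Pa2g4 at 3049 against 109 and Pcbd1 at 5631 against 423. Hbs1l, Rpf2, Tsfm, Mettl1, Lss, Eea1, Gtf3c6, Cpm, Sgpl1, Nrbf2, Socs2 and March9 were the other members, and the lowest ratio of cluster 2 over cluster 4 among the 19 was 8.18, for Socs2 (7.23 to 9.28). They were spread from 21295979 to 128565934, with 15 other expressed genes within 100000 bases of them at a median log2 ratio of -0.06, against 0.15 for 231 genes elsewhere on the chromosome. Single neighbors lay far from 0, such as Nup107 (1.62), Zc3h10 (1.60), Dot1l (1.15) and Os9 (-0.96). Between single cells of cluster 2, Mdm2 ranged from 530.5 CPM at the 5th percentile to 6532 at the 95th. The cells were of like depth, with medians of 18851 UMIs in cluster 2 and 21029 in cluster 4.

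**Figure D4:**
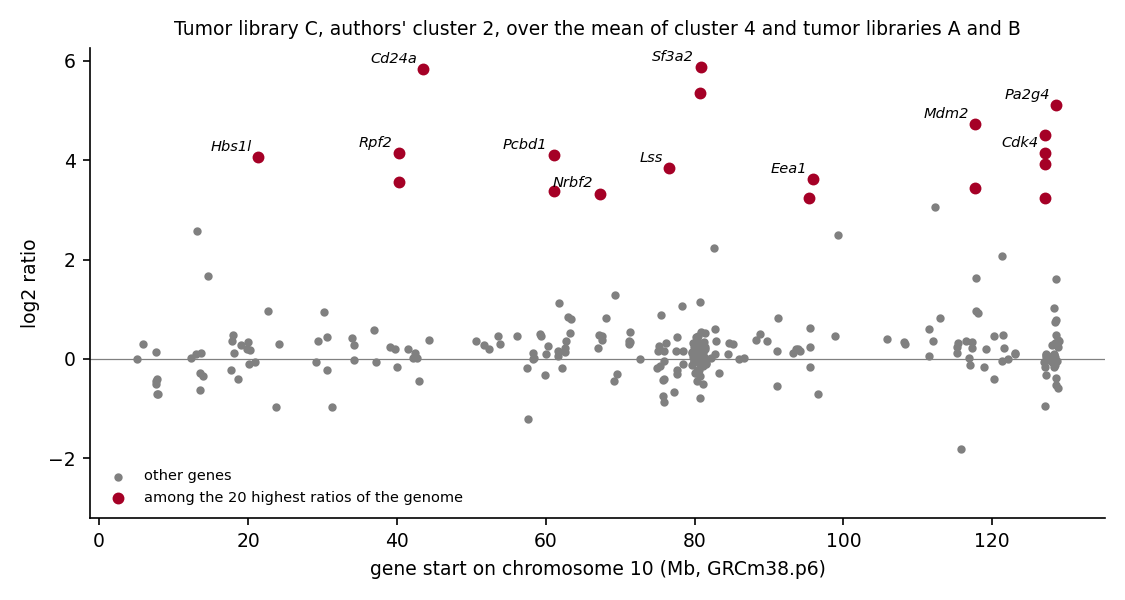
Log2 ratio of each expressed gene of chromosome 10 in cluster 2 of tumor library C over the mean of cluster 4 and tumor libraries A and B, by gene start (Mb); red points are the 19 genes among the 20 highest ratios of all chromosomes. These genes lie between 21295979 and 128565934 bases; 15 other genes within 100000 bases of them have a median of -0.06, with single ones such as Nup107 at 1.62, Zc3h10 at 1.60 and Os9 at -0.96.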

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

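The tests of scaling and of the longest and shortest genes were chosen after the results were seen. So were those of the stress genes in other cell types and of free RNA in alpha cells. The same holds for those of the clusters and the share of top genes on chromosome 10. Those of gene length against random sets and of stress genes in tumors were not. The test of the neighbors on chromosome 10 was set before its own result, but for a comparison chosen after the values were seen. A transcript named tdTomato, a red fluorescent reporter that no comparison above uses, was present in all 5 libraries, with no library without the reporter to serve as control. It stood at 524.3 CPM in heterozygous and 385.2 in homozygous alpha cells, and at 738.8, 699.5 and 965.0 in tumor libraries A, B and C, all pooled over cells. The median cell went the other way in part, with 472.9 and 300.6 CPM in islet alpha cells and 288.5, 217.4 and 330.4 in the tumors. Pooled over cells, endothelial cells held 387.5 CPM in the heterozygous and 328.5 in the homozygous library, beta cells 333.0 and 282.9, and stellate cells 133.3 and 57.9. Heterozygous macrophages held 135.9 CPM. In tumor library C it stood at 1214 CPM in the median cell of cluster 2 and at 207 in that of cluster 4.

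Of the genes that differed between tumors and islet alpha cells, 213 of 227 were higher in tumors. Their median log2 change was 1.87 (quartiles 1.48 to 2.45) before and 1.603 (1.188 to 2.197) after TMM scaling, with a median SE of 0.292 in both. TMM scaling moves all genes of a library by 1 factor, and the median tested gene went from 0.246 to -0.041. Genes picked for a large change had to stay high, so the test cannot decide about the share of hormone transcripts in the totals. At an unadjusted p under 0.05 by limma, 1923 genes were higher and 269 lower before, and 916 and 1010 after. The excess of higher genes at that level thus depended on the scaling. After TMM scaling 35 of the higher calls stayed past the threshold, and why single calls ended was not tested. If introns had been counted in the islet tables alone, long genes would be lower in tumors; the median log2 change of the 998 longest genes lay 0.138 above that of the 998 shortest, which goes against it, while the called genes were short (percentile 0.26 among random sets), which goes with it. Of 16 stress and immediate early genes 5 were higher and 2 lower in every tumor library than in both islet libraries. The 2 go against a rise of the whole list, and handling in different sessions and tumor biology cannot be told apart for these genes. Tissue and table are confounded, and a biological difference stays open.

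Stress and immediate early genes were far lower in homozygous than in heterozygous alpha cells. Handling that raised them in every cell type of the heterozygous library by a like amount would lower them as far in endothelial cells, where the median log2 ratio was -0.142 (lowest -1.035) against -2.83 in alpha cells. Free RNA from other cell types would leave Fos at a small part of the endothelial level, but in heterozygous alpha cells it stood at 101.3% of it. The other 15 genes stood at a median of 47.5%, from 2.55% for Ier3, 14.0% for Dusp1 and 19.5% for Junb to 135.0% for Hspa1a, so for them free RNA and expression by alpha cells cannot be told apart. The median log2 ratio was -1.64 in delta and -0.62 in beta cells; in stellate cells it was -0.68, with 11 of 16 genes below 0 and a range of -1.77 to 2.483. Handling that acted unequally on cell types may still be the source. An effect of the genotype stays open as a hypothesis, with 1 library each.

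The genes of chromosome 10 raised in cluster 2 of tumor library C were tested again on genes chosen without cluster 4. Of the 20 genes highest in cluster 2 over tumor libraries A and B, 13 lay on chromosome 10, and these stood in cluster 2 at a median of 13.78 times their level in cluster 4 (lowest 9.249). The other 7 lay between 0.133 and 3.984 times. Free RNA or doublets shared evenly by the cells of 1 library would not give such a difference. However, the clusters rest on the same expression values, so a difference between them was partly built in. The 13 genes also stood higher in cluster 4 than in tumor libraries A and B, such as Mdm2 (168 against 49.5 and 44.9 CPM). Whether free RNA gave that part was not tested. Of the top 20 genes over the mean that includes cluster 4, 19 lay on chromosome 10, so a gain of segments of that chromosome may be the source. Other genes within 100 kb had a median log2 ratio 0.21 below that of the rest of the chromosome (-0.21). This median left out the 19 raised genes, also where they neighbored each other, so it cannot decide whether neighbors rose together. A gain of small pieces and a transcriptional program of scattered genes cannot be told apart without DNA data. Of the 19 genes, 12 had another of them within 100 kb, against a median of 2 and a highest value of 11 in 10000 random draws. DNA was not analysed here.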

How the results depend on the processing

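The alternatives edgeR with TMM, edgeR without low filter, limma after TMM scaling, totals without hormones, deposited values, a pseudocount of 10, the single homozygous clusters, and edgeR and leave-one-out on the thinned split were chosen after seeing the data; the others were planned. No paired analysis was possible because the labels do not tie a tumor library to an islet library. A Leiden resolution of 0.5 was not run because the authors' types were used.

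Tumors against islets gave 213 genes higher and 14 lower. DESeq2 gave 453 and 318, of which 216 were shared with these calls, edgeR with TMM 26 and 9, edgeR without low filter 587 and 390, and edgeR with library size only 104 higher. With no low filter limma called 6 higher and 0 lower (2786 and 840 at an unadjusted p under 0.05), where more genes were tested. Limma after TMM scaling gave 35 and 9, totals without hormones 44 higher, deposited values 663 and 24, the marker gate, which took in islet cells of other types, 463 and 103, and the homozygous islet library alone, assumed to vary like the tumors, 13 and 0 (2186 and 68 unadjusted). Leaving out each library gave 13 to 142 higher and 0 to 23 lower. Beyond the number of genes and libraries, the cause was not tested. With 2000 or more UMIs, doublets kept or a pseudocount of 10 the counts stayed within 1.5 times.

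Slc38a5-positive against negative cells gave 20 higher and 8 lower. DESeq2 gave 0 and 0 (42 and 22 at an unadjusted p under 0.05), 2 or more Slc38a5 UMIs gave 0 and 0 with limma (380 and 176), and no library block 0 and 0 (10 and 6). EdgeR with TMM gave 51 and 31, and with library size only 62 and 30. The thinned split over all 5 libraries gave 5 and 1, with 3 calls shared, and 77 and 56 with edgeR; without 1 library it gave 0 to 22 higher and 0 to 10 lower: 22 and 10 without the heterozygous islets, 4 and 3 without the homozygous, 1 and 0 without tumor library A, 2 and 0 without B, and 0 and 0 without C (1193 and 114 unadjusted by limma). Hspa1a changed direction in 1 of these, to 0.27 without tumor library A. Without a library block the difference between genotypes enters the spread; otherwise the cause was not tested.

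The Slc38a5 ratio of homozygous over heterozygous alpha cells was 7.92, and 9.44 without the 8 hormone transcripts in the totals, 11.2 with cluster 2.1 alone and 2.02 with cluster 2.2 alone. The share of alpha cells in homozygous islets was 56.4% with 2000 or more UMIs. Slc38a5-positive shares not thinned were 40.9% in heterozygous and 82.8% in homozygous islets and 97.2%, 99.8% and 99.5% in tumor libraries A, B and C, since deeper cells give more chances of a UMI. With 2 or more UMIs they were 4.25%, 52.7%, 75.8%, 92.4% and 90.1%. Cycling shares not thinned were 11.5%, 10.1% and 14.0% in the tumors, and with 3 or more genes 3.80% in B and 4.12% in C, against 0.772% and 0.421% in the islets, where the intervals of B (2.61 to 5.32) and of heterozygous alpha cells (0.0937 to 2.76) overlapped.

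With an estimated correlation no gene list called with the preset stayed past the threshold. The adjusted p was 0.343 for cell cycle and peptide hormones, 0.384 for amino acid transporters, 0.413 for hormone processing and the unfolded protein response, and 0.462 for mitochondrially encoded genes in tumors, and 0.815 for the 4 lists of positive cells. Correlation alone does not account for this, since its estimate was -0.016 for amino acid transporters in tumors, below the preset of 0.01, and 0.011 for antigen presentation in positive cells. With an estimate camera also takes the few residual degrees of freedom in place of the number of genes, and these causes were not separated.

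Of the values of named genes under all alternatives, 348 in the tumor comparison kept direction and side of the threshold, 243 kept the direction but missed it, and 1 passed it anew. In the positive against negative comparison these were 167 and 154, with the 1 change of direction above. Of the ratios between islet genotypes 143 stayed within their interval and 102 moved beyond it. Depth limits Gcgr in tumors, where 0 to 3 UMIs were found, and the cycling shares of islets, which rest on 2 and 7 cells.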

Other observations

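The test of resemblance to a cluster was chosen after the result was seen. Nearly all alpha cells of homozygous islets fell into a pair of clusters with different hormone content, with 15 in cluster 2.6. Cluster 2.1 held Slc38a5 at 1087 CPM, Gcg at 350600, Ppy at 28700 and Pyy at 55930, while cluster 2.2 held Slc38a5 at 195, Gcg at 286000, Ppy at 158900 and Pyy at 132100. The tumors had Ppy at 2350, 275.5 and 540.3 CPM, below both clusters. Endothelial cells of the homozygous library held Ppy at 10590 CPM, above each tumor library, so background may account for part of this difference.

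Tumors may share the expression state of the Slc38a5-high cluster. Of 45 genes that differed between the clusters, 84.44% lay on the side of cluster 2.1 in tumor library A, 91.1% in B and 86.7% in C, against 37.8% in heterozygous alpha cells. Of these genes 41 were higher in cluster 2.1, and the 4 lower ones were evenly divided between the sides in tumor libraries A and C and mostly on its side in B, so the share rests mostly on genes higher in that cluster. Of the other 1524 genes 65.4%, 79.1% and 73.4% lay above the midpoint in the tumors, so part of this goes with a rise of most genes, and the question stays open. The resemblance does not show from which cells the tumors arose.

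In cluster 4 of tumor library C, Ins2 stood at 1289 CPM in the median cell and at 24240 at the 95th percentile, and 58 of 385 cells lay above 10000. Tumor libraries A and B held 0.198 and 2.04 CPM. The female transcript Xist and the Y-linked gene Ddx3y differed between libraries, with Xist at 1463 and 1730 CPM in tumor libraries A and B and 0.276 in C, and Ddx3y at 68.4 CPM in tumor library C and 0.396 and 0.398 in A and B, so sex is not balanced in the tumor comparison. In heterozygous and homozygous islet alpha cells Xist stood at 1.24 and 0.135 CPM and Ddx3y at 46.02 and 37.2, so tumor libraries A and B differed in sex from both islet libraries.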
